A study of Mus musculus with 6 samples.

How the data were processed

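RNA from granulosa cells of Fzd1 knockout (KO) and wild-type (WT) mice was measured on 1-colour expression arrays, 3 samples per genotype, and the groups and replicate numbers were taken from the sample titles. The table analysed was the authors' deposited table of processed values, with 30832 labelled rows and 1 column per sample. The deposited values were treated as log2 levels, because they spanned a range that log2 scanner intensities have. The transformation, background correction and between-array normalization behind them are not given in the sources used here. Each array's quantiles were nearly equal and no row centring was visible, but the scale itself stays an inference, so differences are stated on the log2 scale of the deposited values. Many rows lay in a narrow band near the lowest values, where differences between samples have little room. A further 12 columns of per-sample values, 6 of intensity and 6 of detection p-values, carried column names that match no sample label, and they were not used here. Of the row labels, 16202 were symbols of the RefSeq annotation of GRCm38.p6, 5802 were listed there only as synonyms, and 8828 were neither, such as clone names and 5 labels of spike-in RNA. No row was left out for its label, because the labels did not follow the levels.

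The tests had been set before the data were examined for intensities with detection p-values. Because the columns of that kind could not be given a sample, the deposited log2 values were tested instead, with the filter set in advance for a table without detection p-values, the 60% of rows with the highest mean over all 6 arrays. This left 18499 rows. The background correction and quantile normalization set in advance together with that filter were not applied in the main fit. KO minus WT was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, over all 6 arrays and without covariates, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The prior had 1.70 degrees of freedom. A limma-trend fit with robust eBayes, in which the prior spread depends on the level, was an alternative. Rows with a mean above 8 among those tested, 5184 in number, are called off the floor, a limit chosen after the data were examined. The number of arrays limits the precision, which is given as 95% confidence intervals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

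Whether the symbols follow the levels was checked over all 30832 rows. The median level of the rows in each of 24 symbol classes was set against 10000 random lists of the same size, and the number in the brightest 10% of rows was tested with Fisher's exact test, two-sided, adjusted over the classes. The classes were ribosomal proteins, olfactory with vomeronasal receptors, and 22 lists fixed before the data were examined, 14 of pathways or gene groups and 8 of markers of cell types. This check was chosen after the data were examined. A further class, subunits of the respiratory chain, ATP synthase, proteasome, chaperonin and eIF3, was set against random lists in the same way, with the outcome that each explanation requires written before its levels were looked at. The lists were tested for a shift between genotypes with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives.

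The rule set in advance for named genes took Fzd1, the 12 genes with the largest change in each direction among those past the threshold whose KO and WT values did not overlap, skipping clone-type names, up to 6 members past the threshold of each list, and 17 genes of ovulation, gonadotropin response, steroidogenesis and WNT signalling whatever their result, with the brightest probe standing for a gene. Where fewer than 10 genes passed, it took the 10 smallest p-values in each direction. It was not applied, because the symbols could not be taken to name the rows. Instead the row labelled Fzd1 and 4 rows chosen after their values were seen are described, those with the largest difference and the smallest p in each direction, and each is called by its label only. The label of 1 further row, counted among the list members, is not reported here.

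Distances between arrays and principal components used the rows off the floor. All 10 splits of the 6 arrays into 3 and 3 were refitted. The alternatives tried were no filter, stricter filters, limma-trend, array weights, the replicate number as a block, each array left out, another threshold, other set tests, and another centring or normalization of the deposited values. The fit was tested on simulated data with the residual spread of the 18499 rows, 200 of them off the floor shifted in each of 10 draws. limma recovered 36.65% of the shifted rows at a shift of 0.5 log2 units, 82.3% at 1 and 98.05% at 2, and 5.78%, 5.89% and 5.04% of its calls were false. These shares hold for 200 rows shifted by the same size, with each row's residual spread taken as its true spread. They are not the power of the real comparison, where the number of changed rows is unknown. For a simulated list of 25 rows off the floor, camera gave an unadjusted p under 0.05 in 1 of 10 draws with no shift. With a shift of 0.1 it did so in 10 of 10. The simulated rows varied independently and shared the same shift. The fixed lists held 4 to 38 tested rows, were not restricted to rows off the floor and were adjusted over 22 lists. The simulation therefore does not give the power for those lists.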

Results

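Granulosa cells are the somatic cells that surround the oocyte in the ovarian follicle, and Fzd1 encodes Frizzled 1, a cell-surface receptor for WNT ligands. Their RNA was compared between female C57BL/6J mice without Fzd1 (KO) and with it (WT), 3 samples per genotype. Mice aged 23 to 26 days were given 5 IU of eCG, a gonadotropin that drives follicle growth, and 48 h later 5 IU of hCG, which acts on the follicle as the ovulatory surge of luteinizing hormone does. The cells were released from punctured ovaries 12 h after hCG. The comparison asks which transcripts differ without Fzd1 in granulosa cells under an ovulatory stimulus. The labels do not say whether samples of a genotype came from separate animals, so p-values measure the spread between these samples, which may be technical.

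Each array gave 30832 rows, each with a label, which for 16202 was a gene symbol of the RefSeq annotation and for a further 5802 a synonym listed there. The median level was 7.64, 7.64 and 7.65 log2 units on the KO arrays and 7.65, 7.65 and 7.64 on the WT arrays. The 75th percentile lay between 7.76 and 7.77, and the highest value between 14.6 and 15.1. No row had identical values on any pair of arrays, and Pearson's r across rows was between 0.985 and 0.993 for the 15 pairs, so high rows were high on each array. Rows are not independent replicates, and these correlations describe the arrays only.

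The symbols carried by the rows did not follow the levels. Ribosomal proteins are encoded by some of the most abundant transcripts of animal cells, yet the 65 rows with their symbols had a median level of 7.64, as did all 30832 rows. That median stood at the 48.7th percentile of random lists of the same size, for which the 95% range was 7.63 to 7.66. Of these rows 10 were among the brightest 10% of all rows, against 6.5 from an even spread (Fisher's exact p = 0.147, two-sided, adjusted p = 0.970). Olfactory and vomeronasal receptors are genes of sensory neurons, and the 1244 rows with their symbols also had a median of 7.64. Of these, 129 were among the brightest 10%, against 124.4 from an even spread, and their levels reached 12.03. Among the 100 rows with the highest means, 0 carried a ribosomal protein symbol and 0 an olfactory or vomeronasal one, where an even spread would give 0.211 and 4.03. For the olfactory and vomeronasal symbols this is fewer than an even spread, as correct labels would also give, and it was not tested.

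Rows with single symbols of abundant transcripts lay at low, middle and high levels. The row labelled Gapdh, a glycolytic enzyme abundant in most cells, lay at 7.61, percentile 18.2 of all rows, and the row labelled Eef1a1, a translation elongation factor, at 7.59, percentile 4.79. The rows labelled Tpt1 and Rplp0 lay at 7.61 and 7.64, percentiles 24.6 and 53.3, whereas those labelled Ppia and Actb lay at 7.72 and 9.17, percentiles 72.1 and 94.6. Rows labelled with granulosa genes were spread out. Those labelled Inha, a subunit of inhibin, and Star, the cholesterol carrier of steroidogenesis, were at 7.94 and 9.45, and those labelled Cyp11a1, the side-chain cleavage enzyme, and Ptgs2, the prostaglandin synthase induced at ovulation, at 7.65 and 7.61. The rows of the steroidogenesis list had a median of 7.64, at the 65.0th percentile of random lists, and those of the preovulatory granulosa list 7.65, at the 82.8th. None of the 24 symbol classes passed the test for more or fewer bright rows than an even spread (smallest adjusted p = 0.970, Fisher's exact test). The fixed lists are short, with 0.9 to 5.8 rows expected among the brightest 10%, so not passing says little for them. Of the steroidogenesis rows 6 of 31 were there, against 3.1 from an even spread, and of the preovulatory granulosa rows 4 of 39, against 3.9. Because the ribosomal rows as a set lay at ordinary levels, symbols are used only as row labels. No difference between genotypes is attributed to the gene that a label names.

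**Figure D1:**
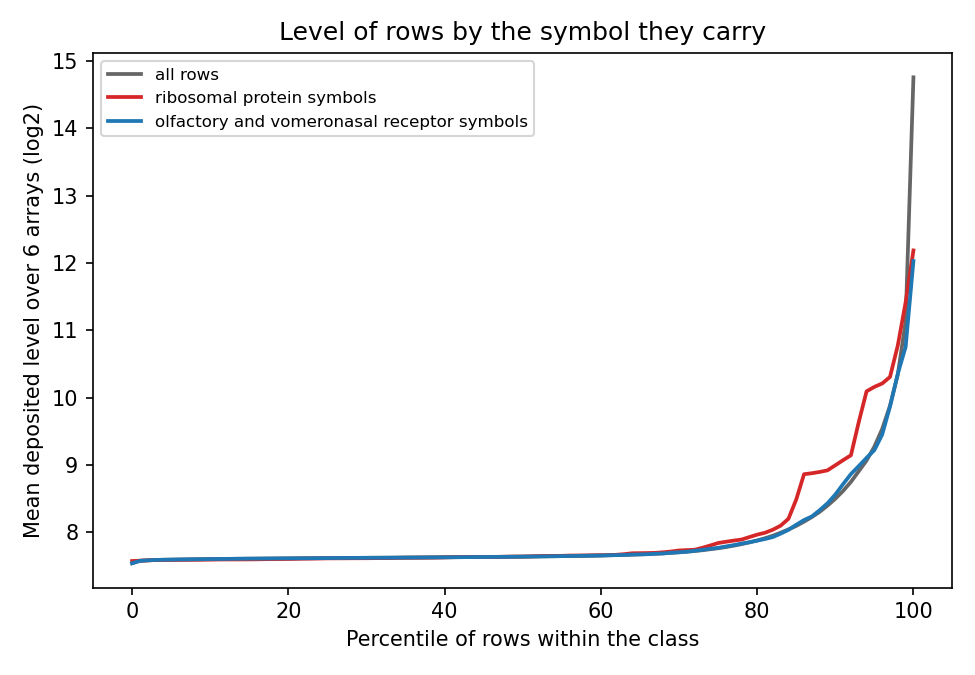
Mean deposited level over the 6 arrays (log2, vertical axis) at each percentile of rows (horizontal axis), for all 30832 rows, the 65 rows with ribosomal protein symbols and the 1244 rows with olfactory or vomeronasal receptor symbols. The curves share a median of 7.64, and at the 90th percentile they stand at 8.50 for all rows, 8.99 for the ribosomal and 8.56 for the olfactory and vomeronasal symbols.

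The row labelled Fzd1 was to be the check of the genotype labels. Its levels were 8.85, 8.80 and 9.10 on the KO arrays (mean 8.92 ± 0.16 SD, n = 3) and 8.69, 8.79 and 8.84 on the WT arrays (8.78 ± 0.075 SD, n = 3). KO minus WT was 0.14 (SE 0.087, 95% interval -0.075 to 0.35), with an adjusted p of 0.978 in limma, and the difference was 0.049 without KO replicate 3. The exact two-sided permutation p was 0.2, and 3 arrays against 3 cannot give less than 0.1. Because the symbols did not follow the levels, this row checks nothing about the genotypes, and the position of its probe relative to the deleted part is not given in the sources used here.

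No row passed the threshold between KO and WT. Of the 18499 rows tested with limma, 0 were higher and 0 lower in KO at an adjusted p of 0.05, and the smallest adjusted p was 0.285. At an unadjusted p under 0.05 there were 913 rows, 496 higher and 417 lower in KO, where 924.95 would come by chance. At 0.01 there were 180, against 184.99. Off the floor alone these counts were 477 and 122, against 259.2 and 51.84. Rows near the floor therefore gave fewer than by chance, and the totals do not show that p-values were evenly spread at each level. limma-trend also called 0 rows, with a smallest adjusted p of 0.456 and 897 rows at an unadjusted p under 0.05. Over all 15 alternatives, most of them other filters or arrays left out of the limma fit, the smallest adjusted p ran from 0.204 with no filter to 0.999 with the replicate number as a block. In 1912 rows (10.3%) the KO values did not overlap the WT values, and chance gives 10% for 3 against 3.

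The differences were small against their intervals. The median absolute difference was 0.024 log2 units and the median half-width of the 95% interval was 0.073. In 11 rows the difference was over 0.5 in size, and in 1 row over 1. Off the floor, in 5184 rows, the median absolute difference was 0.066, the median standard deviation within groups 0.11 and the median half-width 0.19, and the interval lay within 1 log2 unit of 0 in 99.2% of rows and within 0.5 in 87.5%. With limma-trend these shares were 99.7% and 92.1%. Of the rows off the floor, 477 (9.20%) had an unadjusted p under 0.05 in limma, against 259.2 by chance, and 271 (5.23%) in limma-trend. The share in limma was 16.4% without KO replicate 3, and limma-trend was not run without that array. It was 4.59% when limma was fitted to rows with a mean above 8 alone. The limma fit used the same prior spread for all levels, and the median standard deviation within groups over all tested rows was only 0.037. Neither limma-trend nor the fit above 8 showed the excess, so it depended on the variance model and is not read as a genotype difference.

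The row with the largest difference was labelled LOC383123. Its levels were 10.26, 9.17 and 8.56 on the KO arrays and 10.72, 11.44 and 11.08 on the WT arrays. KO minus WT was -1.75 (SE 0.45, 95% interval -2.87 to -0.63), with an adjusted p of 0.952 in limma. The exact permutation p, two-sided, was 0.1, the smallest possible. The smallest adjusted p, 0.285 in limma, belonged to the row labelled 4921505C17Rik. Its mean was 8.40 ± 0.0065 (SD, n = 3) in KO and 8.66 ± 0.024 (SD, n = 3) in WT, a difference of -0.26 (SE 0.019). In limma-trend its adjusted p was 0.967. In the other direction the largest difference was 0.91 (SE 0.34, adjusted p = 0.978 in limma), in the row labelled C80008. The smallest p belonged to the row labelled Sftpc, with a difference of 0.32 (SE 0.034, adjusted p = 0.661 in limma). In limma-trend that row had the smallest adjusted p of all, 0.456. These 4 rows were chosen after their values were seen, and none passed the threshold.

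**Figure D2:**
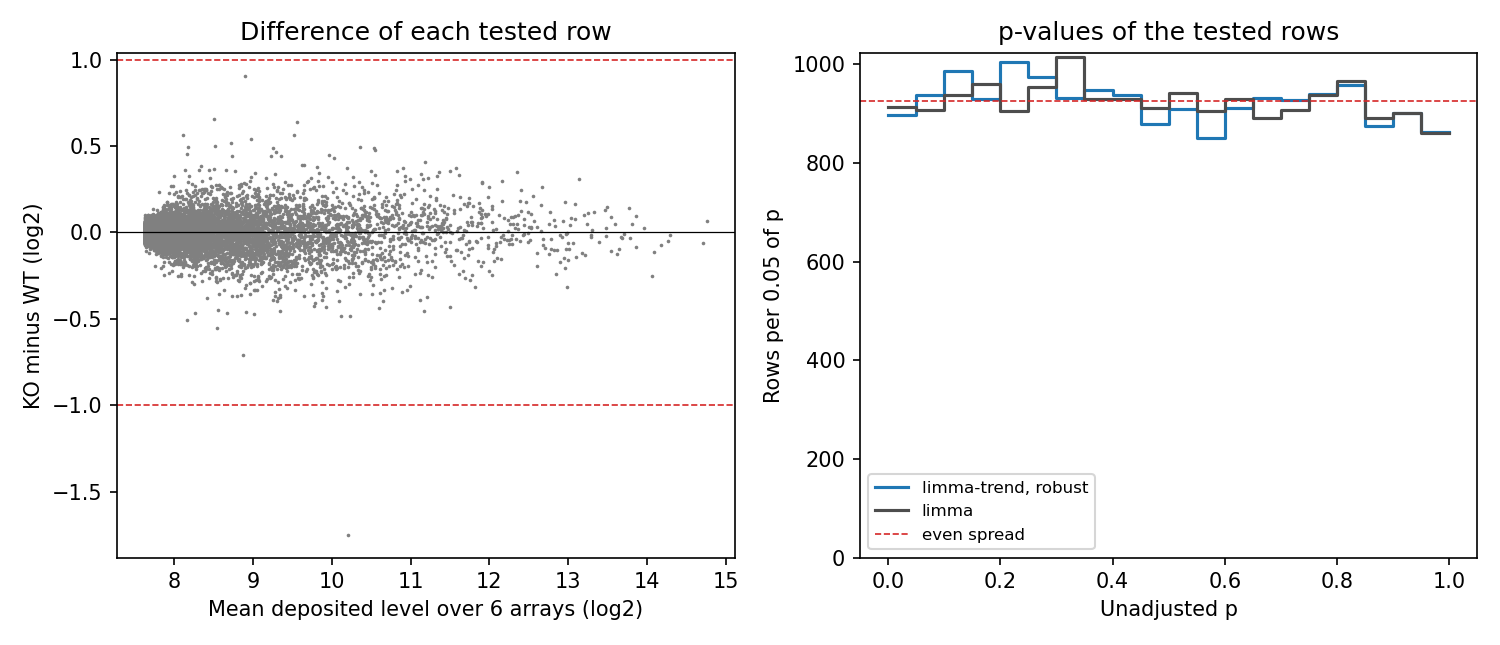
Left, KO minus WT (log2, vertical axis) against the mean deposited level over the 6 arrays (log2, horizontal axis), with a point for each of the 18499 rows tested and dashed lines at -1 and 1. Right, the number of rows in each step of 0.05 of the unadjusted p in limma and in limma-trend, with a dashed line for an even spread. Differences ran from -1.75 to 0.91, and both fits stayed near the even spread at low p, with 913 and 897 rows under 0.05. In limma the 913 joined more rows off the floor than by chance with fewer near it.

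The rows carrying the symbols of the 22 fixed lists were tested as sets, 343 places in the lists being filled by a tested row. No list passed camera (smallest adjusted p = 0.984 in limma), and 0 lists had an unadjusted p under 0.05. With an estimated correlation the smallest adjusted p was 0.983. fry gave a smallest adjusted p of 0.406 for movement in one direction and 0.129 for either direction, and the smallest adjusted p for a directed shift ran from 0.406 to 0.989 over the alternatives. The medians of the lists ran from -0.019 for the leukocyte markers to 0.048 for the theca markers. For the WNT receptors, the ligands with their extracellular modulators and the intracellular pathway the medians were 0.0078, 0.0048 and 0.00078. For ovulation with cumulus expansion and for steroidogenesis they were -0.0027 and 0.010. In 7 of the 22 lists the mean had the opposite sign to the median, among them the leukocyte markers (0.00090), the WNT ligands with their modulators (-0.0032) and the intracellular WNT pathway (-0.027). Over all rows 0 members passed, and adjusted over the list alone 1 did. Given how the symbols relate to the levels, these values describe sets of labelled rows and not pathways or cell types.

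The arrays of a genotype were about as far apart as arrays of different genotypes. Off the floor, Pearson's r across rows was 0.969 to 0.988 within KO, 0.979 to 0.987 within WT and 0.971 to 0.985 between them, with means of 0.977, 0.983 and 0.980. The mean distance between genotypes exceeded that within them by 0.039, 4 of the 10 splits of the 6 arrays gave as large a value (exact p = 0.4, one-sided, smallest possible 0.1), and the highest of the other splits gave 2.49. The sign of this value turned when WT replicate 1, 2 or 3 was left out (-0.643, -0.951 and -0.115), and it was 0.379, 0.495 and 1.07 without KO replicate 1, 2 or 3. The first principal component held 40.4% of the variance and ran from -6.90 for KO replicate 2 to 10.8 for KO replicate 3. On the second, with 19.9%, the KO arrays lay between 2.94 and 5.95 and the WT arrays between -5.84 and -0.93. Chance parts 3 arrays from 3 on a given axis in 10% of cases, and there are 5 axes.

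**Figure D3:**
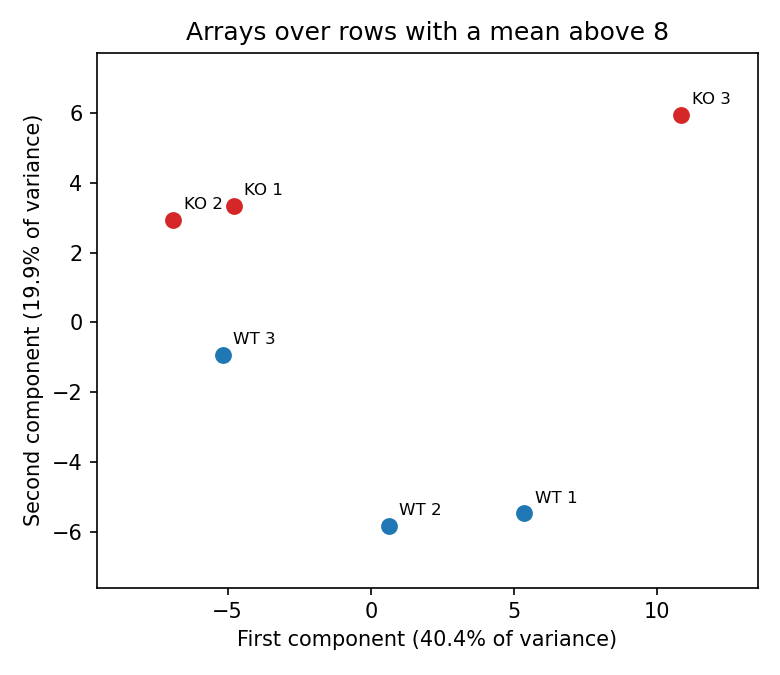
The 6 arrays on the first 2 principal components of the 5184 rows off the floor, with KO in red and WT in blue, and the percent of variance on each axis. KO replicate 3 stands at 10.8 on the first component, the other KO arrays at -4.78 and -6.90, and the WT arrays between -5.17 and 5.36.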

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

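Centring or quantile normalization of the deposited values and the filters to the brightest 30% of rows or to means above 8 were chosen after seeing the data; the other alternatives were planned. Of 196 recomputed values, 189 kept their direction and their side of the threshold, or moved by at most 1.5 times for a count and under 5 percentage points for a share. The limit of 5 points was set after seeing the data. It is wide, so moves of the share off the floor from 9.20% to 5.23% in limma-trend and to 4.59% above a mean of 8 counted as kept. The distance was judged by its sign alone. Part of the agreement was fixed in advance. The filters, limma-trend and the replicate block cannot alter a row's difference, so only its p could move. The distance always used the rows off the floor, so the filters could not alter it. In limma, 0 rows were higher and 0 lower in KO under all 15 alternatives, an adjusted p of 0.1 included, with smallest adjusted p-values from 0.204 to 0.999, and no list passed under 16 alternatives (0.406 to 0.989). Rows at an unadjusted p under 0.05 numbered 1485 with no filter, 465 in the brightest 30% and 238 above a mean of 8, where more or fewer rows were tested, and 714 to 1329 with 1 array left out. The share off the floor was 8.20% to 16.4% in limma with 1 array left out, highest without KO replicate 3. It was 4.59% in the fit to means above 8 and 5.23% in limma-trend, which was not run with arrays left out. With 1 array left out, between minus within distance was -0.951 to 1.07. It turned negative without WT replicate 1 (-0.643), 2 (-0.951) or 3 (-0.115). Leaving out a WT array gives the KO pairs more weight in the mean within genotypes. Off the floor, mean r was 0.977 within KO and 0.983 within WT. Whether this weighting accounts for the sign was not tested separately. The row labelled Fzd1 differed by 0.049 (without KO replicate 3) to 0.198. With the replicate number as a block, 0 rows were higher and 0 lower and 775 had an unadjusted p under 0.05. Deviations of same-numbered KO and WT arrays correlated at -0.215, -0.038 and -0.321, so no shared deviation by number was seen. Arrays of different number were not compared, so this cannot tell whether samples were collected or hybridised in pairs. Background correction, scaling after it and detection filters were not run, since they need the columns not used here. A slide block was not run, since no batch is given in the sources used here. Averaging of probes and counting genes in place of probes were not run, since the symbols could not be taken to name the rows. Whether the floor is background was not tested, so what signal over background limits is not known here.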

Other observations

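The tests were chosen after the result was seen, except the splits behind the rows past the threshold, the further class of abundant transcripts and the relation of the leading axis to level.

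The rows with ribosomal protein symbols lay at ordinary levels. Compression of dim values by the processing keeps the order of rows and would leave over 50% of them among the brightest 10%, but 15.4% were there (exact 95% interval 7.63% to 26.5%), which argues against it. Symbols paired with the wrong rows would also put other abundant classes inside the range of random lists. The 138 rows with symbols of the respiratory chain, ATP synthase, proteasome, chaperonin and eIF3 had a median of 7.63, at percentile 7.01 of random lists (95% range 7.63 to 7.65), with 9 among the brightest 10% against 13.8 from an even spread. A candidate explanation is a mismatch of symbols and values in the table; where it arose was not tested. No biological explanation was tested.

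No row passed the threshold between KO and WT in limma. With 0 rows in the real split, all 10 splits of the 6 arrays necessarily gave as many, which says nothing about chance; the highest of the others gave 1. As many rows had an unadjusted p under 0.05 in 3 of 10 splits, with 913 in the real split and 1792 in the split that set KO replicates 1 and 2 with WT replicate 3 against the rest. The splits are too few for a share under 0.05. If the arrays were too few to exclude a change of 1 log2 unit, most intervals off the floor would reach that size. In limma-trend 99.7% lay within it, which argues against too few arrays for single rows off the floor on the deposited scale. The intervals are not adjusted over rows, so they do not show that such a change would have passed the threshold. In the simulation limma recovered 82.3% of rows shifted by 1, with 200 rows shifted. The spread between samples may be technical, and then the intervals do not cover differences between animals. Smaller effects of the genotype, effects in rows near the floor and effects shrunk by the authors' processing stay open.

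The leading axis of variation between arrays held 40.4% of the variance off the floor. Genotype as its source would put all KO arrays on one side, but 3 WT arrays lay between the lowest and highest KO array. KO replicate 3 made up 48.2% of the squared scores on the axis, between the 83.3% of an axis set by 1 array alone and an even share of 16.7%. The other 5 arrays spanned -6.90 to 5.36 on it, and without that array the leading axis, which need not be the same one, held 41.2%. The 48.2% lies between the reference shares, so it cannot tell whether KO replicate 3 alone is the source. Likeness among the other arrays also enters the axis. A level-dependent trend left by the normalization would tie the loadings to the level, and Spearman's rho across rows was -0.0315. A difference in handling or hybridisation may also be its source and was not tested, since no batch is given in the sources used here.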
